A study of Homo sapiens with 14 samples.

How the data were processed

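RNA sequencing measured gene expression in MGE-like progenitor cells, a culture model of the medial ganglionic eminence of the ventral forebrain, made from the human embryonic stem cell line H9. Per the labels, cells received SB431542 at 2 µM and LDN193189 at 200 nM from day 0 to day 6, which block TGF-beta and BMP signalling. SHH at 250 ng/mL and the smoothened activator purmorphamine at 0.3 µM were given from day 10 to day 17, and neurospheres were kept in suspension until collection at day 25. The 14 libraries fall into 4 groups: wild type (WT, n = 3), knockout of CTNNB1, the gene of beta-catenin (KO, n = 5), inducible CTNNB1 overexpression without doxycycline (OE without Dox, n = 3), and the same line with doxycycline at 0.1 µg/mL from day 17 to day 25 (OE with Dox, n = 3). Libraries were made from 500 ng of total RNA. The labels do not say whether replicates are separate differentiations, nor which form of CTNNB1 was overexpressed or how the knockout was made. No WT library received doxycycline, so the drug and the transgene are not separable.

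The deposited values are a normalized signal: gene read counts divided by the authors by 1 size factor per library. This was tested on the values: in each library all low values are whole multiples of 1 step, which lies between 0.866 and 0.947 per read, and 100.0% of values are whole reads at a tolerance of 0.01. The table has 58051 Ensembl genes. The submitters' processing notes name TopHat2 2.1.1, HTSeq 0.9.1, R 3.4.0, DESeq2 without a version and genome build hg38, with no roles or order. Neither the annotation release nor the strand setting of the counting is given. The recovered reads assigned to genes number between 5233270 and 5639725 per library. A count of 0 allows up to 3 reads, which is a normalized count between 2.60 and 2.84 per library. Such floors cover counting error only, because reads without molecular identifiers are not independent molecules. Between libraries of 1 group, the squared differences were 3.83 to 13.94 times those of counting error alone over 19 pairs, so on average over genes libraries differ by more than counting error. Differences between cultures and between library preparations are not separated in that value.

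Names and coordinates come from GENCODE 44, which names 56948 of the identifiers and leaves 1103 without a name. Genes with a normalized count of at least 10 in at least 3 of the 14 libraries were tested, which were 17102 genes, 16996 of them named. The test was limma 3.58.1 in R 4.3.3 on log2 of the normalized count plus 1, with 1 model of all 14 libraries and 4 groups, an intensity trend and robust empirical Bayes, 10 residual degrees of freedom, two-sided, and Benjamini-Hochberg adjustment at 0.05 within each comparison. The planned comparisons were KO against WT, OE with Dox against OE without Dox (the Dox effect), OE without Dox against WT, and the difference between the Dox effect and the KO effect. KO against OE without Dox and OE with Dox against WT were added after the control groups were seen to differ. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

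The 35 gene lists were fixed before the data were examined, and so were the tests, most alternatives and the rule for named genes. The 33 lists with at least 5 tested members were tested with camera at a preset correlation between genes of 0.01. They were tested again with an estimated correlation, which is the stricter form of camera, and with fry, each adjusted over the lists. List calls below are those of camera unless fry is named. The fry test asks whether the members of a list shift at all, while camera compares them with the other genes. Where many genes change, a fry call alone therefore does not set a list apart from other genes. Lists share members, among them 7 of the 18 dorsal telencephalon genes, 4 of 30 WNT ligands and receptors and 4 of 14 MGE markers, so their results are not independent. The rule names CTNNB1, the 8 genes with the largest rise and the 8 with the largest fall in each main comparison among those with adjusted p under 0.05, a mean of at least 100 and no overlap between the groups, 4 of each for the control comparison, up to 4 called members of each list by adjusted p, or up to 2 of highest mean where none is called, and among genes called in both main comparisons the 8 most opposed and the 4 most alike. XIST, Y-linked genes and names of pseudogenes, antisense, LINC, LOC and clone genes were left out. Of the 227 genes the rule names, those printed here are a selection made after their values were seen, which favours genes whose call holds when any 1 library is left out.

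Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, TMM and upper-quartile scaling, empirical Bayes without the robust option, sample quality weights, the replicate number as a block, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, a fit of the 2 compared groups alone, and leaving out each library. Chosen after seeing the data were the exchange of the control group and the removal of WT 1, KO 1 and KO 2 together. In counts drawn at random with the mean levels and spread of these libraries, limma recovered 65.2% of genes changed 2-fold and 93.9% of those changed 4-fold in the KO against WT layout. In the layout of the Dox effect it recovered 40.3% and 93.9%. The draws changed 66 or 67 genes at each of these folds, far fewer than were called in the data, so these shares need not hold there. Nothing in the table was left out except genes under the filter.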

Results

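The question was how loss and gain of CTNNB1 change the transcriptome of H9-derived MGE-like progenitors at day 25. Levels are mean normalized read counts ± SD, with n = 5 for KO and n = 3 for each of WT, OE without Dox and OE with Dox. Folds are log2 folds from limma, and p is adjusted by Benjamini-Hochberg over 17102 genes unless a list is named. Counts of called list members are to be read beside the calls over all 17102 genes. These were 1136 higher and 1223 lower in KO against WT, and 2189 and 2204 with Dox.

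CTNNB1 (ENSG00000168036, hg38 chromosome 3, 41194741 to 41260096, plus strand) stood at 3814 ± 573 in WT, 2383 ± 271 in KO, 3345 ± 276 in OE without Dox and 27060 ± 3820 in OE with Dox. The KO level was lower than WT by a log2 fold of -0.67 (SE 0.13, adjusted p = 0.001), and all 5 KO libraries, at 2090 to 2779, lay below the 3 WT libraries, at 3248 to 4393. Transcript from the gene was therefore still abundant in KO, at 0.626 of the WT level. With Dox the level rose by a log2 fold of 3.01 (SE 0.14, adjusted p = 5.8e-11), in 3 of 3 libraries. OE without Dox did not differ detectably from WT (log2 fold -0.18, adjusted p = 0.55).

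**Figure D1:**
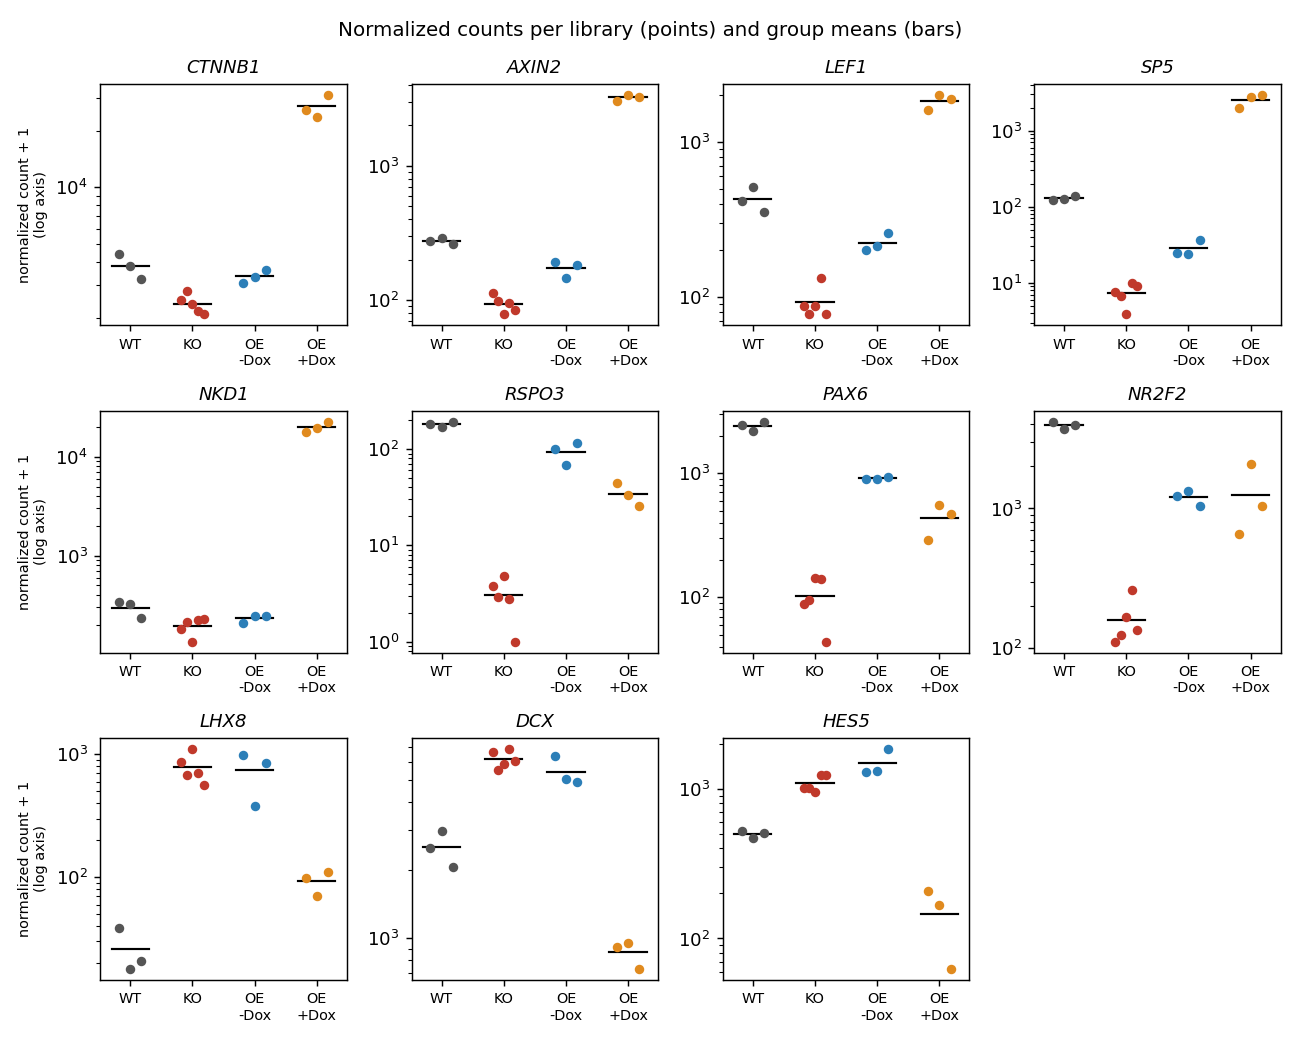
Normalized read counts plus 1 (log axis) of 11 genes by group: points are single libraries and bars are group means. CTNNB1 is lowest in KO and highest in OE with Dox, AXIN2, LEF1 and SP5 follow the same order, and LHX8 and DCX are at similar levels in KO and OE without Dox.

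Large falls in KO included genes of the dorsal forebrain and of WNT signalling. RSPO2, a secreted enhancer of WNT signalling (chromosome 8, 107899316 to 108083642), went from 498 ± 211 in WT to 2.39 ± 0.799 in KO, and OTX1 from 808 ± 164 to 6.69 ± 3.31. WNT7B fell from 895 ± 157 to 11.7 ± 6.18, TPBG from 2839 ± 265 to 68.0 ± 15.3, GDF7 from 405 ± 70.7 to 10.2 ± 4.83, and NR2F2 from 3943 ± 226 to 159 ± 60.7. Higher than in WT were the MGE regulator LHX8 (24.9 ± 11.3 to 786 ± 212) and FZD5 (393 ± 306 to 3510 ± 707). The microRNA host genes MIR9-1HG (19.9 ± 14.6 to 546 ± 158) and MIR9-3HG (49.9 ± 23.7 to 1297 ± 209) rose too, with the strand of the counted reads unknown. Log2 folds of these genes in the test were between -7.15 (RSPO2, adjusted p = 1.9e-10) and 5.03 (MIR9-1HG, adjusted p = 0.00047). Against OE without Dox, RSPO2 (100 ± 55.6 there; log2 fold -4.80), OTX1 (184 ± 35.5; -4.69) and NR2F2 (1198 ± 148; -2.97) were lower in KO as well. LHX8 (740 ± 319; 0.16) did not differ detectably from it, with an adjusted p of 0.98.

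WNT feedback targets fell as a group in KO: of 18 tested, 0 were higher and 13 lower (0 and 13 adjusted over the list alone). AXIN2 fell from 275 ± 13.2 to 93.4 ± 13.3, LEF1 from 427 ± 81.5 to 91.3 ± 22.9, SP5 from 128 ± 9.66 to 6.40 ± 2.38, and TNFRSF19 from 391.5 ± 130 to 21.2 ± 6.07. The list median was a log2 fold of -1.29 (camera adjusted p = 8.5e-13; adjusted p = 0.0052 with an estimated correlation). Of 28 WNT ligands and receptors 4 were higher and 18 lower (4 and 19 adjusted over the list alone), with RSPO3 down from 180 ± 10.8 to 2.05 ± 1.40 and FZD1 from 443 ± 19.9 to 98.5 ± 21.8 (adjusted p = 0.0089 with an estimated correlation). Both lists were also lower in KO than in OE without Dox, with 0 higher and 6 lower, and 0 higher and 10 lower (adjusted p = 0.007 and 0.0049 with an estimated correlation).

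Regional markers moved in opposite directions. Of 17 markers of dorsal telencephalon and cortical hem 0 were higher and 13 lower (1 and 14 adjusted over the list alone), among them PAX6, from 2403 ± 204 to 101 ± 41.0, and WNT8B, from 201 ± 48.0 to 2.03 ± 1.05. LMX1A went from 146 ± 21.3 to 0.925 ± 0.920, which is 5 reads over the 5 KO libraries. Of 13 LGE and CGE markers 0 were higher and 9 lower (0 and 11 adjusted over the list alone), including NR2F1, from 2894 ± 113 to 575 ± 194, and ZNF503, from 501 ± 128 to 28.0 ± 3.90. The 10 choroid plexus genes had 0 higher and 5 lower (0 and 6 adjusted over the list alone), with TRPM3 down from 273 ± 61.5 to 26.3 ± 11.9. MGE markers had 6 higher and 2 lower of 14 (8 and 2 adjusted over the list alone): GBX1 rose from 7.20 ± 1.68 to 40.4 ± 12.7 and GSX1 from 16.5 ± 1.54 to 77.3 ± 16.5, while SHH fell from 648 ± 192 to 143 ± 50.5 and OLIG2 from 300 ± 78.4 to 165 ± 33.2. With an estimated correlation the adjusted p was 0.003 for dorsal markers, 0.0052 for LGE and CGE, 0.0068 for choroid plexus and 0.016 for MGE. Against OE without Dox, dorsal (0 higher, 10 lower), LGE and CGE (0 and 7) and choroid plexus genes (0 and 4) were again lower, and MGE markers (0 higher, 1 lower; adjusted p = 0.46 with an estimated correlation) did not differ detectably.

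Hedgehog and BMP genes were lower in KO, and genes of neurons higher. Of 15 SHH pathway genes 0 were higher and 8 lower (0 and 9 adjusted over the list alone; adjusted p = 0.003 with an estimated correlation), with GLI1 down from 184 ± 74.8 to 8.43 ± 2.77 and GLI2 from 562 ± 110 to 50.2 ± 15.5. Of 20 BMP and TGF-beta response genes 1 was higher and 15 lower (1 and 15 adjusted over the list alone; adjusted p = 0.0077 with an estimated correlation), with ID1 down from 232 ± 83.0 to 11.6 ± 5.43 and MSX1 from 100 ± 22.8 to 13.4 ± 4.73. Of 23 genes of neuron structure and synapse 17 were higher and 3 lower (18 and 4 adjusted over the list alone), led by DCX, from 2513 ± 451 to 6174 ± 542, STMN2, from 1807 ± 159 to 4010 ± 333, and RTN1, from 314 ± 22.9 to 1026 ± 240. That list had an adjusted p of 5.3e-09 at the preset correlation and an adjusted p = 0.049 with an estimated correlation. Against OE without Dox the SHH (0 higher, 5 lower) and BMP genes (0 and 9) were lower too, and neuron genes (0 and 2, adjusted p = 0.71 with an estimated correlation) did not differ detectably.

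With camera, other lists were lower in KO than in WT at the preset correlation only. The fry test called G2/M (adjusted p = 0.029), stress (0.012), progenitor (0.00024) and hypothalamus genes (0.0057) lower, and did not call G1/S genes (0.18). G2/M genes had 0 higher and 13 lower of 40 (0 and 20 adjusted over the list alone), with CDC20 at 477 ± 21.2 in WT and 282 ± 42.9 in KO. Camera gave an adjusted p of 1.2e-09 for this list, and adjusted p = 0.32 with an estimated correlation. G1/S genes had 0 higher and 4 lower of 36 (0 and 1 adjusted over the list alone), and CCNE1 fell from 79.4 ± 4.94 to 45.4 ± 8.70. Their adjusted p = 0.62 with an estimated correlation. Genes of unfolded protein and amino acid stress had 0 and 6 of 16 (0 and 9 adjusted over the list alone), and DDIT3 fell from 92.5 ± 21.0 to 39.8 ± 5.77. Their adjusted p = 0.25 with an estimated correlation. Progenitor and radial glia genes had 2 and 8 of 20 (2 and 10 adjusted over the list alone, and adjusted p = 0.1 with an estimated correlation). Among them SLC1A3 fell from 603 ± 161 to 83.1 ± 32.7 and SOX9 rose from 259 ± 54.0 to 982 ± 164. Hypothalamus and ventral diencephalon markers had 3 and 7 of 17 (4 and 9 adjusted over the list alone), and FOXD1 fell from 315 ± 74.2 to 8.93 ± 5.74. Their adjusted p = 0.31 with an estimated correlation. In KO against OE without Dox limma called 0 genes of G2/M, G1/S and the stress list (6, 3 and 1 at an unadjusted p under 0.05, and 0 called by edgeR and by DESeq2). As lists, G2/M (median -0.25, camera adjusted p = 6.8e-09) and G1/S genes (median -0.12, 0.024) were still lower there at the preset correlation. With an estimated correlation they were not called (0.37 and 0.71). The stress list had a median of 0.06. Progenitor genes had 0 higher and 4 lower there and hypothalamus markers 0 and 3.

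Lists of other tissues and of cell junctions were likewise lower in KO than in WT with camera at the preset correlation only. The fry test called mesenchyme (adjusted p = 0.029), neural crest (0.016), epithelium (0.028) and midbrain, hindbrain and spinal cord (0.029) lower. It did not call adherens junction genes (0.059). Mesenchyme had 1 higher and 3 lower of 16 (1 and 4 adjusted over the list alone), with FBN1 down from 351 ± 59.4 to 108 ± 19.1. Neural crest had 0 and 5 of 9 (1 and 5 adjusted over the list alone), with NGFR down from 347 ± 88.6 to 106 ± 43.4. Epithelium had 0 and 4 of 9 (0 and 4 adjusted over the list alone), with KRT19 down from 30.1 ± 11.8 to 9.60 ± 1.23. Midbrain, hindbrain and spinal cord had 0 and 2 of 15 (0 and 2 adjusted over the list alone), with PAX7 down from 42.6 ± 15.8 to 3.33 ± 0.904. These 4 lists each had an adjusted p = 0.31 with an estimated correlation. Adherens junction genes had 2 and 4 of 25 (2 and 6 adjusted over the list alone), with CDH6 down from 871 ± 106 to 280 ± 63.1. Their adjusted p = 0.49 with an estimated correlation.

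The remaining lists were not called in KO with camera, while fry called proneural factors lower (adjusted p = 0.028). NOTCH ligands, receptors and modulators had 2 higher and 4 lower of 17 (2 and 5 adjusted over the list alone). NOTCH1 rose from 1500 ± 411 to 2993 ± 139 and JAG1 fell from 775 ± 211 to 296 ± 53.9. NOTCH targets had 2 and 0 of 9 (2 and 0 adjusted over the list alone), with DTX1 up from 160 ± 16.6 to 294 ± 30.7. Proneural factors had 5 and 7 of 19 (5 and 8 adjusted over the list alone), with MYT1L up from 38.5 ± 10.8 to 91.1 ± 20.1 and NEUROG1 down from 34.8 ± 11.6 to 5.92 ± 3.41. That list was called lower against OE without Dox, with 0 higher and 4 lower (0 and 8 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation). GABAergic genes had 3 and 3 of 19 (6 and 5 adjusted over the list alone). GAD1 rose from 244 ± 26.0 to 687 ± 128 and ERBB4 fell from 693 ± 238 to 38.7 ± 8.68. The median of the GABAergic list, 0.14, and its mean, -0.23, differ in sign. FGF and ERK feedback had 1 and 3 of 15 (1 and 5 adjusted over the list alone) and CDK inhibitors 0 and 3 of 15 (0 and 3 adjusted over the list alone). Pluripotency genes had 0 and 2 of 7 (0 and 2 adjusted over the list alone), with SALL4 down from 631 ± 29.1 to 261 ± 46.6. Of 17 p53 targets 2 were higher and 0 lower (2 and 0 adjusted over the list alone), with SPATA18 up from 63.0 ± 12.2 to 175 ± 22.0. Glia had 0 and 1 of 8 and the interferon response 0 and 1 of 12 (each 0 and 1 adjusted over the list alone). Immediate early genes had 0 and 1 of 15 (0 and 0 adjusted over the list alone). CDK inhibitors, pluripotency genes and glia had medians of 0.07, 0.05 and 0.02 beside negative means and tests. For p53 targets the median was -0.1 beside a mean of 0.01. Of the lists too short to test, endothelium and blood had 0 and 1 of 3 (KDR 20.8 ± 6.92 to 1.84 ± 0.0481) and skeletal and cardiac muscle 0 and 1 of 4. No gene was called by limma among 19 of hypoxia and glycolysis, 13 encoded in mitochondria and 32 of cytosolic ribosomes, over all genes or adjusted over the list alone. At an unadjusted p under 0.05 they had 2, 1 and 3 genes, edgeR called 0 in each, and DESeq2 called 1, 0 and 0. There the hypoxia gene SLC2A1 had an adjusted p = 0.24 (0.018 in a fit of both groups alone), MT-CO1 0.93 and RPL3 0.95.

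In all, limma called 1136 genes higher and 1223 lower in KO than in WT, 536 and 750 of them by at least 2-fold, and 18.1% of tested genes had groups that did not overlap, against 3.57% by chance. Without WT 3, 757 genes were higher. Against OE without Dox in place of WT, 60 were higher and 300 lower, of which 24 and 254 were also called in that direction against WT, with the same KO libraries in both. KO 1, 2 and 3 against WT and KO 4 and 5 against OE without Dox share no library. Between these, 10 genes were higher and 127 lower in both, against 1.5 and 10 for independent lists. MIR9-1HG (log2 fold -0.03), GBX1 (-0.33), SOX9 (-0.09) and DDIT3 (0.04) changed sign when all KO libraries were set against OE without Dox. MIR9-1HG, SOX9 and DDIT3 were then near 0. In that comparison DCX (0.19), STMN2 (0.28), RTN1 (0.34), FZD5 (0.36), GAD1 (0.36), NOTCH1 (0.15), CDC20 (-0.49) and CDH6 (-0.60) kept their sign without being called. At the preset correlation 19 of 33 lists were called, a number that regroupings of the same libraries also gave, and with an estimated correlation 9 were.

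**Figure D2:**
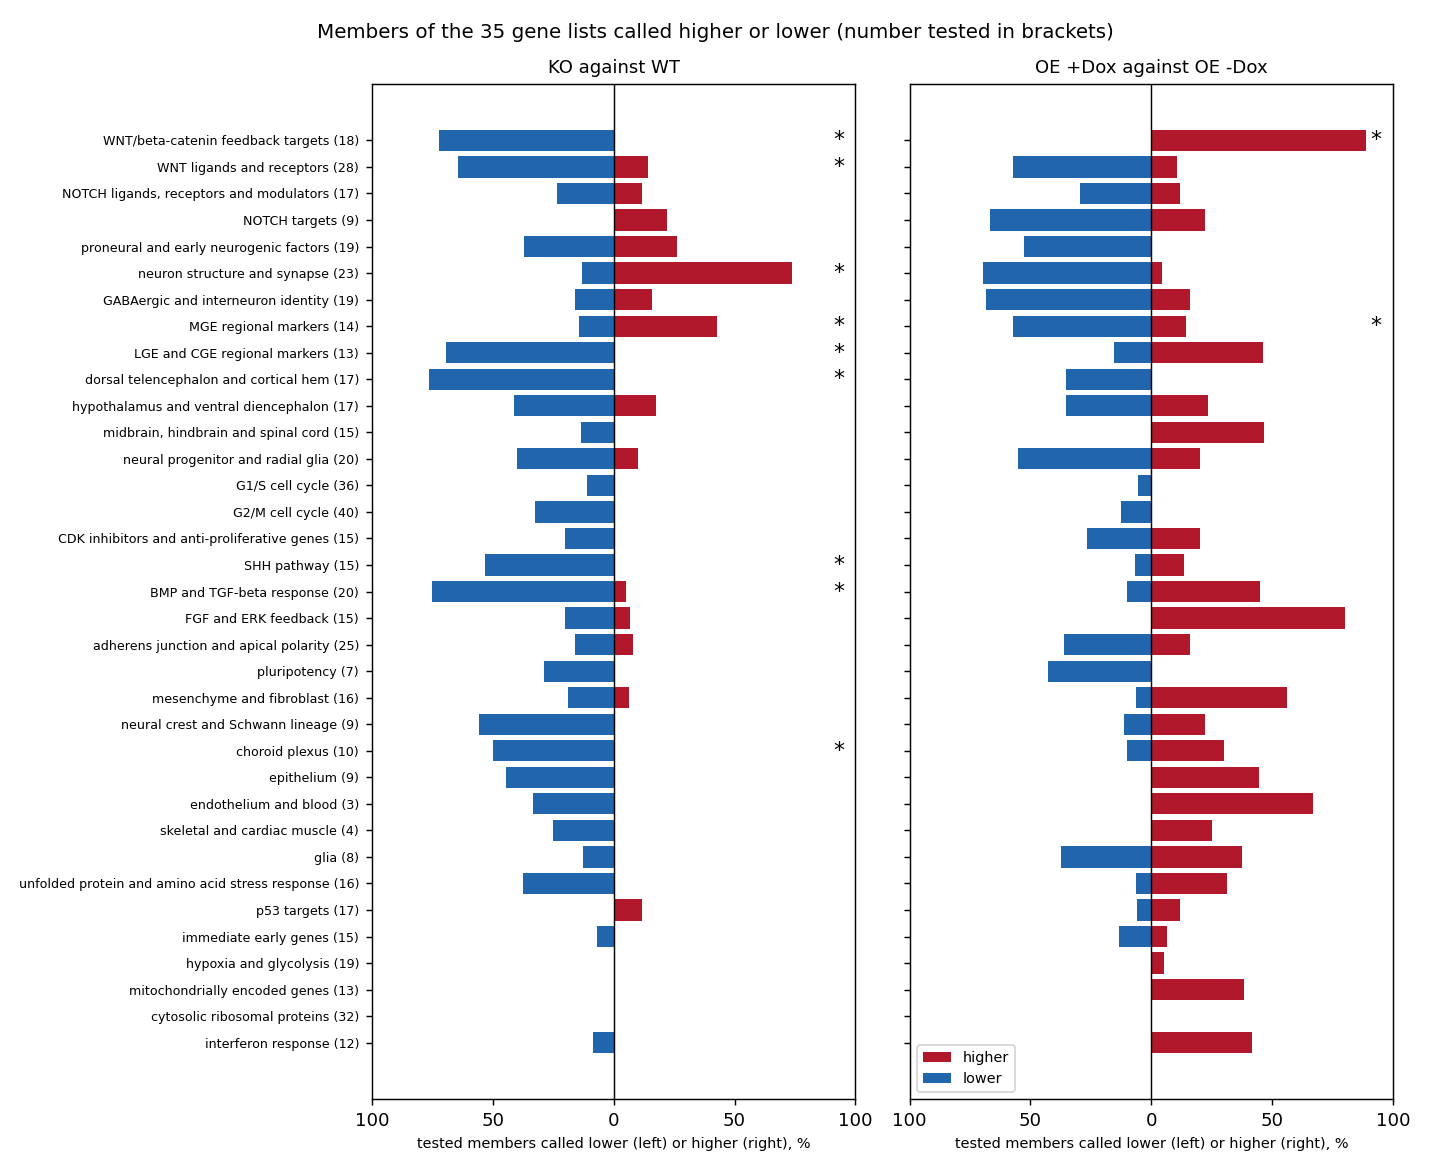
Share of the tested members of each of the 35 lists called lower (blue, left) or higher (red, right), in percent, for KO against WT and for the Dox effect; an asterisk marks an adjusted p under 0.05 with an estimated correlation. WNT feedback targets are lower in KO (13 of 18) and higher with Dox (16 of 18), and the list of MGE markers is marked in both, with opposite directions.

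With Dox, WNT feedback targets had the highest median rise of the lists. NKD1 (chromosome 16, 50548396 to 50649249) went from 232 ± 19.5 in OE without Dox to 20004 ± 2352, SP5 from 27.4 ± 6.88 to 2561 ± 520, AXIN2 from 173 ± 25.4 to 3217 ± 165 and LEF1 from 222 ± 31.1 to 1845 ± 207. The WNT antagonists DKK4 and NOTUM went from 0.617 ± 1.07 to 876 ± 298 and from 2.75 ± 0.0284 to 2083 ± 533, with 2 and 9 reads over the 3 libraries without Dox. FGF20 had 0 reads there and 685 ± 257 with Dox, at least 247-fold higher than the floor of 3 reads per library. Of 18 targets 16 were higher and 0 lower (16 and 0 adjusted over the list alone), with a median log2 fold of 4.49, also with FGF20 at its bound (camera adjusted p = 7.5e-23; adjusted p = 0.0019 with an estimated correlation). WT held these genes at 298 ± 54.8 for NKD1, 128 ± 9.66 for SP5 and 275 ± 13.2 for AXIN2.

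MGE markers were lower with Dox than in OE without Dox. With camera, GABAergic, neuron and proneural genes were lower at the preset correlation only. The fry test called them lower too (adjusted p = 0.00016, 6.3e-06 and 3.4e-05). LHX6 went from 230 ± 162 to 4.32 ± 4.36, LHX8 from 740 ± 319 to 91.8 ± 20.03, OLIG2 from 208 ± 20.9 to 33.3 ± 8.03 and SOX6 from 662 ± 250 to 170 ± 16.5. Of these 4 only LHX8 stayed above its WT level, 24.9 ± 11.3. The MGE list had 2 higher and 8 lower of 14 (3 and 9 adjusted over the list alone, and adjusted p = 0.022 with an estimated correlation). With WT as the control the MGE list had 5 higher and 6 lower and was not called by camera (adjusted p = 0.47 with an estimated correlation). The fry test called it lower there (adjusted p = 0.00075). Of 19 GABAergic genes 3 were higher and 13 lower (3 and 13 adjusted over the list alone, and adjusted p = 0.21 with an estimated correlation). DLX1 fell from 883 ± 336 to 106 ± 51.8 and DLX2 from 571 ± 209 to 57.1 ± 27.6. GAD1 ran against its list, from 591 ± 364 to 2895 ± 396 (log2 fold 2.45, adjusted p = 1e-05). Of 23 neuron genes 1 was higher and 16 lower (2 and 16 adjusted over the list alone, and adjusted p = 0.11 with an estimated correlation), with DCX down from 5429 ± 811 to 866 ± 117. Of 19 proneural factors 0 were higher and 10 lower (1 and 11 adjusted over the list alone, and adjusted p = 0.11 with an estimated correlation).

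With camera, the lists of progenitor, NOTCH target, FGF, BMP and mesenchyme genes were called against OE without Dox at the preset correlation only. The fry test called them in the same directions (adjusted p = 0.0029, 0.00054, 0.00032, 0.00032 and 0.00053). NES went from 8156 ± 1156 to 1536 ± 512 and SOX9 from 1054 ± 222 to 140 ± 50.4, while SLC1A3 rose from 214 ± 76.1 to 5256 ± 1356 and ZIC2 from 339 ± 97.8 to 2625 ± 590. Of 20 progenitor genes 4 were higher and 11 lower (4 and 11 adjusted over the list alone, and adjusted p = 0.31 with an estimated correlation). NOTCH targets had 2 higher and 6 lower of 9 (2 and 6 adjusted over the list alone, and adjusted p = 0.31 with an estimated correlation), with HES5 down from 1485 ± 311 to 145 ± 75.3. FGF and ERK feedback had 12 higher and 0 lower of 15 (14 and 0 adjusted over the list alone, and adjusted p = 0.24 with an estimated correlation). FGF17 rose from 26.6 ± 9.14 to 1338 ± 187 and SPRY2 from 152 ± 28.3 to 1423 ± 76.0. BMP and TGF-beta response had 9 and 2 of 20 (10 and 4 adjusted over the list alone, and adjusted p = 0.31 with an estimated correlation). BMP4 rose from 11.9 ± 1.68 to 459 ± 142 and MSX1 from 44.8 ± 14.9 to 558 ± 142. With WT as the control the BMP list had 5 higher and 6 lower and was not called (median -0.08, camera adjusted p = 0.96). Mesenchyme had 9 and 1 of 16 (13 and 1 adjusted over the list alone, and adjusted p = 0.24 with an estimated correlation). PRRX1 rose from 8.27 ± 4.86 to 269 ± 40.8, and TWIST2 from 1.22 ± 1.06, which is 4 reads over 3 libraries, to 209 ± 9.68.

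Other lists called with Dox at the preset correlation lost that call with the estimated one. WNT ligands and receptors had 3 higher and 16 lower of 28 (3 and 18 adjusted over the list alone, and adjusted p = 0.21 with an estimated correlation). WNT7A fell from 145 ± 26.99 to 14.8 ± 11.7 and FZD10 rose from 11.03 ± 9.77 to 1368 ± 623. Dorsal telencephalon had 0 and 6 of 17 (0 and 7 adjusted over the list alone), with LHX5 down from 156 ± 41.2 to 42.5 ± 14.6. Midbrain, hindbrain and spinal cord had 7 and 0 of 15 (7 and 0 adjusted over the list alone), with IRX3 up from 14.1 ± 5.93 to 190 ± 56.3. Epithelium had 4 and 0 of 9 (4 and 0 adjusted over the list alone), with KRT19 up from 31.5 ± 13.5 to 185 ± 69.7. Pluripotency had 0 and 3 of 7 (0 and 4 adjusted over the list alone), with DNMT3B down from 283 ± 16.4 to 115 ± 14.1. These 4 lists each had an adjusted p = 0.31 with an estimated correlation. The interferon response had 5 and 0 of 12 (5 and 0 adjusted over the list alone, and adjusted p = 0.32 with an estimated correlation). Mitochondrially encoded genes had 5 and 0 of 13 (6 and 0 adjusted over the list alone, and adjusted p = 0.33 with an estimated correlation). MT-CO2 rose from 6496 ± 651 to 10186 ± 1504, and with WT as the control its log2 fold was 0.23 (adjusted p = 0.32). With that control epithelium (2 higher and 0 lower), the interferon response (2 and 0) and mitochondrially encoded genes (1 and 0) were not called at the preset correlation either (adjusted p = 0.053, 0.21 and 0.21). Adherens junction genes had 4 and 9 of 25 (4 and 9 adjusted over the list alone, and adjusted p = 0.5 with an estimated correlation), with CRB2 down from 1636 ± 278 to 567 ± 87.1. G2/M had 0 and 5 of 40 (0 and 1 adjusted over the list alone, and adjusted p = 0.58 with an estimated correlation), with HMGB2 down from 2242 ± 271 to 1438 ± 188. G1/S had 0 and 2 of 36 (0 and 1 adjusted over the list alone, and adjusted p = 0.75 with an estimated correlation), with HELLS down from 567 ± 67.6 to 335 ± 60.4. For both cell cycle lists the share called lower was no larger than that over all genes, 2204 of 17102.

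The lists that follow were not called with Dox by camera. The fry test called NOTCH ligands, receptors and modulators lower (adjusted p = 0.0032), and LGE and CGE markers (0.0017) and SHH pathway genes (0.00076) higher. NOTCH ligands, receptors and modulators had 2 higher and 5 lower of 17 (4 and 5 adjusted over the list alone), and DLL1 fell from 1655 ± 246 to 333 ± 125. LGE and CGE markers had 6 and 2 of 13 (6 and 4 adjusted over the list alone), and PROX1 rose from 118 ± 42.8 to 1856 ± 227. Hypothalamus markers had 4 and 6 of 17 (4 and 6 adjusted over the list alone), and FOXA1 rose from 58.6 ± 56.0 to 805 ± 263. SHH pathway genes had 2 and 1 of 15 (2 and 1 adjusted over the list alone), and DISP1 rose from 65.0 ± 12.01 to 421 ± 127. CDK inhibitors had 3 and 4 of 15 (4 and 4 adjusted over the list alone), with CCNG2 up from 605 ± 74.0 to 2447 ± 197 and CDKN1B down from 851 ± 36.3 to 513 ± 49.3. Neural crest had 2 and 1 of 9 (2 and 1 adjusted over the list alone). Choroid plexus had 3 and 1 of 10 (4 and 1 adjusted over the list alone), and TRPM3 rose from 290 ± 45.7 to 945 ± 92.0. Glia had 3 and 3 of 8 (3 and 3 adjusted over the list alone), and OLIG1 fell from 565 ± 139 to 84.1 ± 20.8. Unfolded protein and amino acid stress had 5 and 1 of 16, p53 targets 2 and 1 of 17 and immediate early genes 1 and 2 of 15, all with the same counts adjusted over the list alone, and JUN fell from 481 ± 113 to 176 ± 26.6. Hypoxia had 1 and 0 of 19 (0 and 0 adjusted over the list alone) and ribosomal proteins 0 and 0 of 32 by limma (6 at an unadjusted p under 0.05, 0 called by edgeR and by DESeq2, RPL3 adjusted p = 0.43). Medians and means differed in sign for CDK inhibitors (-0.39 and 0.16), choroid plexus (-0.27 and 0.02) and hypoxia (-0.17 and 0.17). For immediate early genes the test pointed down beside a median of 0.13. Endothelium and blood, with 2 and 0 of 3, and muscle, with 1 and 0 of 4, were too short to test, and KDR rose from 14.4 ± 10.9 to 87.0 ± 31.6.

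In all, 2189 genes were higher and 2204 lower with Dox (1825 and 2508 with upper-quartile scaling), 1226 and 1252 by at least 2-fold. Groups did not overlap for 40.7% of genes, against 10% by chance. Against WT in place of OE without Dox, 1773 genes were higher and 1725 lower in OE with Dox, and 1323 and 1231 of these were called in the same direction in both, against 226.9 and 222.3 for independent lists. The same OE with Dox libraries enter both comparisons, which makes such calls agree. Blocking by the replicate number, which pairs OE libraries with and without Dox, gave 2467 higher and 2454 lower.

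The control groups differed from each other. In OE without Dox against WT, LHX8 rose by a log2 fold of 4.81 (adjusted p = 2.2e-06), MIR9-3HG of 4.46 (0.0014) and DCT, from 18.1 ± 12.6 to 263 ± 71.7, of 4.00 (0.0009), while WNT1 fell from 208 ± 75.7 to 21.3 ± 9.95. Of 18 WNT feedback targets 0 were higher and 9 lower (0 and 9 adjusted over the list alone; adjusted p = 0.036 with an estimated correlation), of 14 MGE markers 6 higher and 0 lower (7 and 1 adjusted over the list alone; 0.012) and of 15 SHH pathway genes 0 higher and 3 lower (0 and 4 adjusted over the list alone; 0.03). Neuron genes had 9 higher and 0 lower of 23 (16 and 1 adjusted over the list alone; adjusted p = 0.065 with an estimated correlation). Immediate early genes had 0 and 1 of 15 (0 and 7 adjusted over the list alone; median -1.49) and unfolded protein and amino acid stress 0 and 2 of 16 (0 and 9 adjusted over the list alone; median -0.56). Both were called lower at the preset correlation (adjusted p = 5.2e-06 and 2.4e-06) and not with an estimated correlation (0.24 and 0.17). limma called 586 genes higher and 396 lower, with 23% of genes in groups that did not overlap against 10% by chance. The counts rest on few libraries: 299 and 157 were called without WT 3, 267 and 152 without OE without Dox 1, and 338 and 205 without OE without Dox 3, while without WT 2 253 were lower. Of the genes called, 500 were higher and 321 lower in KO than in WT as well, and 0 went the opposite way. Both comparisons use the same WT libraries: their log2 folds had a Pearson r of 0.761 across genes, and 20 simulated draws without any change gave a mean of 0.5548. Without change that r is set by the shared group and the group sizes, so it does not give the part of the agreement due to sharing. The covariance of the folds was 0.313, against a simulated mean of 0.0499, so it was larger than noise shared through the WT libraries gives. The draws hold no shift common to all WT libraries and do not address one.

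With WT as the control for KO, many genes changed in opposite directions in KO and with Dox. SP5 fell in KO (log2 fold -4.19) and rose with Dox (6.5), and TMEM132C, from 104 ± 25.2 to 4.57 ± 4.14 in KO, rose from 70.5 ± 3.46 to 3485 ± 1186 with Dox. GRIK1 (-4.03 and 4.34), GCNT1 (-3.92 and 4.24) and FOXB1 (-4.05 and 3.99) did the same, and MIR9-3HG (4.79 and -4.77) went the other way. With WT as the control for OE with Dox, FOXB1 (0.93, adjusted p = 0.22) and MIR9-3HG (-0.31, adjusted p = 0.8) were not called. NTRK2, from 1346 ± 121 to 86.5 ± 40.7 in KO and from 604 ± 312 to 64.5 ± 30.1 with Dox, CDH20 (-3.21 and -3.11) and ADCY2 (-3.05 and -3.02) fell in both. Of genes called in both comparisons, 640 were higher in KO and lower with Dox, where independent lists would give 146.4, and 475 were lower in KO and higher with Dox, against 156.5. In the same direction, 73 rose in both, against 145.4, and 149 fell in both, against 157.6. Among genes changed at least 2-fold in both comparisons, 32 rose in both, against 38.4, and 85 fell in both, against 54.9. Of these larger changes 289 were higher in KO and lower with Dox, against 39.2, and 291 the reverse, against 53.8. The 1115 opposed and 222 shared genes come from comparisons with no library in common, and across genes the log2 folds had a Pearson r of -0.333 and a Spearman rho of -0.371, where genes are not independent replicates. With OE without Dox as the control for KO, 20 and 109 genes were opposed, against 7.7 and 38.4 for independent lists, and 8 rose and 56 fell in both, against 7.7 and 38.7. That pair shares the OE without Dox libraries, which by itself makes folds of KO and Dox alike. A test of the difference between the Dox effect and the KO effect called 2589 genes with a higher and 2331 with a lower Dox effect (2130 and 2791 with upper-quartile scaling), and CTNNB1 differed by a log2 fold of 3.68 (adjusted p = 1.4e-10).

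**Figure D3:**
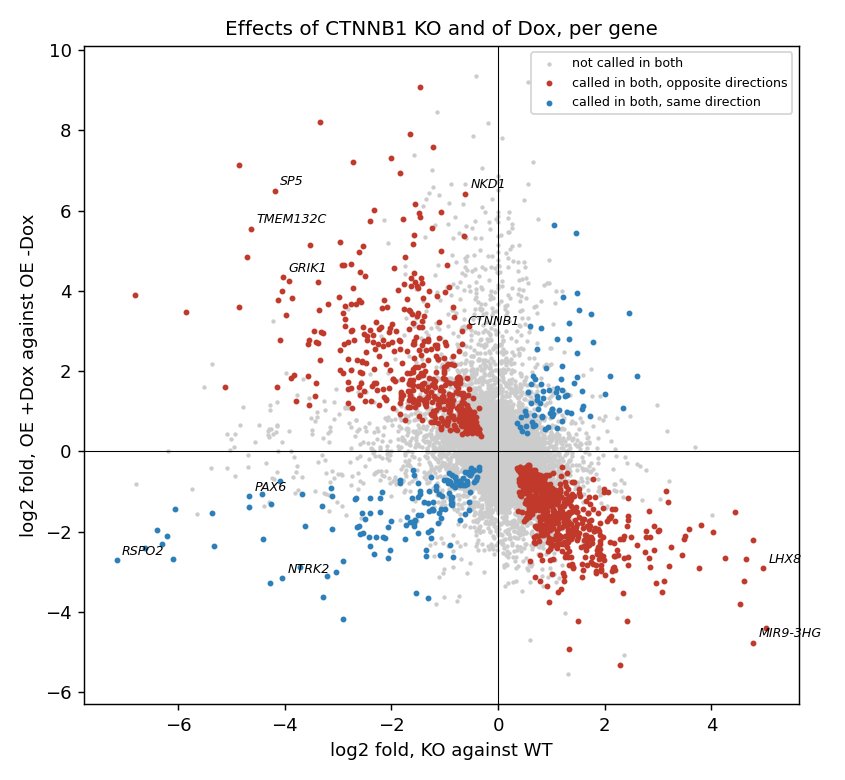
Log2 fold of KO against WT (x axis) and of the Dox effect (y axis) for each tested gene; red points were called in both comparisons with opposite directions and blue points with the same direction. Of the genes called in both, 1115 are red and 222 blue.

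The libraries grouped by label. The first principal component of the log2 values held 50.3% of the variance and set OE with Dox, at 95.2 to 108.4, apart from the other libraries, at -51.1 to 2.9. The second held 15.5% and set WT, at 52.1 to 62.6, apart from the rest, and OE without Dox, at -4.3 to 8.3, lay between WT and KO, at -30.3 to -20.6. Pairwise correlations across genes were 0.916 to 0.95 between KO and WT and 0.951 to 0.971 between KO and OE without Dox, against 0.970 to 0.982 within KO.

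**Figure D4:**
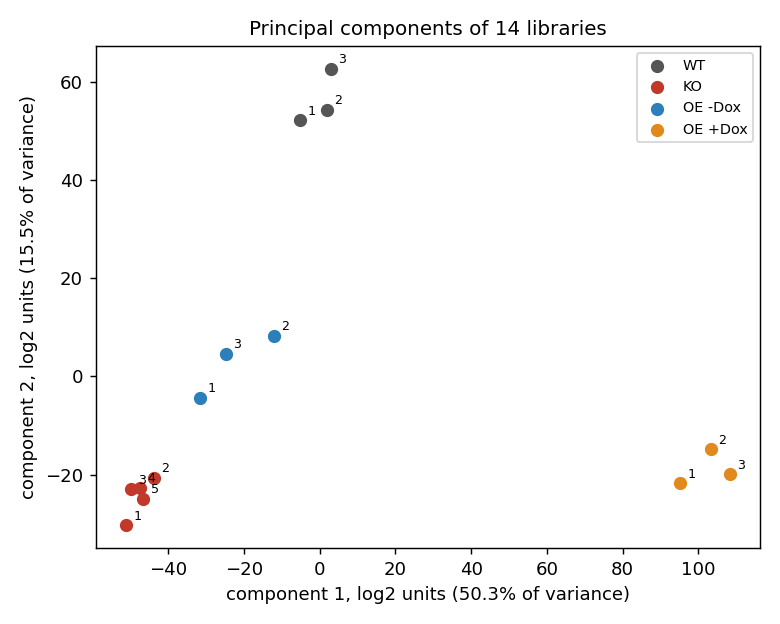
First and second principal components of log2 values for the 14 libraries, in log2 units, with replicate numbers beside the points. OE with Dox lies to the right at 95.2 to 108.4, WT at the top at 52.1 to 62.6, and OE without Dox between WT and KO.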

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

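All tests of explanations in this part were chosen only after the results were seen. The regroupings of libraries were planned, with 2 exceptions. Those of KO against OE without Dox came with that comparison, which was added after the control groups were seen to differ. Those of list counts with an estimated correlation were chosen after the count at the preset correlation turned out to be matched by regroupings.

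Within the group of 5 KO libraries, 130 values were tested. These were the named genes, the reads assigned to genes, the mitochondrial and top 10 gene shares of reads, and the genes with a read. In 6 of them, all named genes, 1 library stood apart from the other 4 by more than a critical ratio of 0.71 of gap to range. Chance alone exceeds that ratio in about 1 of 20 groups, so 6 is no more than chance gives. The groups of 3 libraries were not tested. LEF1 was at 131 in KO 4, against 76.1 to 86.9 in the other 4. FGF18 was at 0 in KO 1, against 1.79 to 1.89, a difference of 2 reads. ETV4 was at 35.9 in KO 2, against 10.4 to 12.9. TFAP2A was at 2.77 in KO 1, against 4.47 to 4.72. PAX3 was at 10.8 in KO 4, against 4.47 to 4.72. VCAM1 was at 315 in KO 3, against 27.7 to 94.3.

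Genes higher in KO than in WT were mostly nearer to the KO level than to the WT level in OE without Dox, where a lower CTNNB1 transcript was not detected. Of the 1136 higher genes 901 (79.3%) had the same sign in KO against OE without Dox and 24 were called there, with the same KO libraries in both comparisons, which by itself favours the same sign. Their median log2 fold was 0.96 in KO against WT and 0.19 in KO against OE without Dox, a ratio of 0.20 with quartiles over genes of 0.03 to 0.34. A candidate explanation is that the WT cultures differ from both engineered lines for a reason other than CTNNB1. The ratio restates the pattern on genes picked by their fold against the same WT libraries, so it neither supports nor excludes that. For the 1223 lower genes the ratio was 0.36 with quartiles of 0.19 to 0.62. What part of either change comes from the WT cultures and what part from CTNNB1 cannot be told apart, because the line and the culture differ together between the groups. Lower WNT output in OE without Dox is also open as an explanation, since the WNT feedback targets there had a median of -0.75 against WT.

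WT 1, KO 1 and KO 2 deviated from their group means in the same direction along the largest component within groups, which held 23.7% of the variance within groups (37.3, 26.4 and 25.1, against -26.7 to -10.6 in the other WT and KO libraries). The first replicate was also positive in OE without Dox (16.4) and OE with Dox (16.3), and the third was negative in all 4 groups (-26.7, -12.5, -22.6 and -22.1). The tables argue against library depth, as 0 of the 3 libraries lay outside the range of reads of the other 5 WT and KO libraries. Mesenchymal cells, read from COL1A1, COL1A2, COL3A1, LUM and DCN, are argued against by ranges that overlapped (a gap of -0.72), with both KO 1 (0.11) and KO 2 (-0.18) inside the range of the other 5. Oxygen or glucose supply, read from the hypoxia list, stays open: WT 1 (0.76) and KO 1 (0.41) were the highest of the 8 libraries, and only KO 2 (-0.15) lay below the highest of the other 5, a gap of -0.26 that rests on 1 library. In the OE groups the list did not follow the component in replicates 1 and 2. Replicate 2 was highest (1.28 without Dox, 0.99 with Dox) at components of 6.2 and 5.7, and replicate 1 stood at -0.22 and -0.03. Replicate 3 was lowest in both (-1.06 and -0.96), as on the component. The labels give no batch, so a day of culture or of library preparation shared by replicate number stays open too.

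Mesenchyme genes were higher in OE with Dox, and among the libraries without Dox the sum of COL3A1, COL1A2, LUM and DCN was highest in WT 2, at 1536, and OE without Dox 2, at 1314, against 342 or less in the others. More of the cells behind those counts may seem the simplest explanation, but TWIST2 and PRRX1 together stood at 15.7%, 9.43% and 39.1% of that sum with Dox, against 0.582% in WT 2 and 1.2% in OE without Dox 2. The lowest of the 3 was 7.87 times the higher of those 2 values, which argues against more of the same cells as the whole cause. On the other side, WT 1 already had 17.4% on a sum of 147 counts, and KO 1 7.07%. A few abundant genes drawing reads are argued against too, since the share of reads in the 10 most abundant genes differed by 0.67 percentage points. A response of progenitors to CTNNB1 or to the drug, and another mesenchymal type, were not tested and stay open.

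Regroupings of the 8 KO and WT libraries gave 1 of 56 splits with as many called genes as the real 2359, the real one itself, and the highest other split gave 505. A random grouping is thus an unlikely source of that count if the libraries are independent. The labels do not say whether they are, so the regroupings exclude chance only on that condition. For KO against OE without Dox the real count of 360 was reached by 1 of 56 splits and the highest other gave 3. For the Dox effect (4393 genes, highest other 0) and the control comparison (982, highest other 1) the 10 possible splits are too few for a share under 0.05; where replicate numbers pair the libraries, the 3 other splits that part all 3 pairs gave at most 0 in both. The difference between the Dox effect and the KO effect called 4920 genes, and 1 of 100 drawn splits gave as many. The highest other gave 3170. The 1115 opposed and 222 shared genes were each reached by 1 of 100 drawn splits, with a highest other of 0. A gene counts there only if called in both comparisons, and other splits of the OE libraries called 0 genes for the Dox effect. That outcome was thus nearly set in advance, and it does not bear on whether the changes are opposed.

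For gene lists the result differed by test. In KO against WT, 19 lists were called at the preset correlation, and 6 of 56 splits gave as many, the highest 26, so chance cannot be excluded for that number. With an estimated correlation 9 lists were called, and 1 of 56 splits gave as many, with 1 list at most in the others. In those other splits the difference between KO and WT enters the residuals from which the correlation is estimated, which lowers their counts. The contrast with the preset correlation is thus partly built in. Regroupings were not run for fry. The 9 are not independent, since lists share members (RSPO2, WNT8B, WNT2B and WNT3A are in both the dorsal and the WNT ligand list). For the Dox effect 20 lists were called at the preset correlation (highest other 17) and 2 with an estimated correlation (highest other 0), and 10 splits are too few for a share under 0.05.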

How the results depend on the processing

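The exchange of the control group and the removal of WT 1, KO 1 and KO 2 together were chosen after seeing the data; the other alternatives were planned.

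The counts of genes stayed within 1.5 times the reported ones under pseudocounts of 0.5 and 5, no filter, a filter of 50, TMM and upper-quartile scaling, empirical Bayes without the robust option, sample quality weights, the fit of 2 groups, edgeR and DESeq2, except that DESeq2 called 595 genes lower in OE without Dox against WT in place of 396; the cause was not tested. With the replicate block, KO against WT had 1107 higher and 1376 lower and the Dox effect 2467 and 2454. Replicate numbers 4 and 5 occur only in KO, so the block term absorbs KO 4 and KO 5. The KO effect then rests on KO 1, 2 and 3 alone, and the block is no check of all 5 KO libraries. The replicate numbers pair OE without Dox with OE with Dox and with WT, by deviations that correlate at 0.17 to 0.40, and do not pair WT with KO (-0.29 to 0.24). WT and OE with Dox pair clearly at number 3 only (0.25). Number 1 gave 0.06 against 0.04 for the best other number, and number 2 gave 0.04 against 0.11. The pairing is therefore incomplete. The edgeR counts were 1194 and 1224 for KO and 2180 and 2240 for Dox, and edgeR also made 2290 of limma's 2359 KO calls and 4274 of its 4393 Dox calls in the same direction. The median log2 fold of all genes moved by less than 0.1 between scalings in each comparison of 2 groups, and for the difference of effects from 0.05 as deposited to -0.07 with upper-quartile scaling. The larger side turned with that scaling in KO, to 1318 higher and 1075 lower, and in the difference of effects, to 2130 and 2791, so neither side can be called the larger. The near balance of the Dox effect also depended on scaling, with 1825 higher and 2508 lower under upper-quartile scaling.

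With OE without Dox as the control, KO had 60 genes higher and 300 lower. At an absolute log2 fold of at least 1 in both, 580 genes were opposed and 117 shared, a stricter call by construction. The correlation of KO and Dox folds moved from -0.333 to -0.265 without a filter, where genes near 0 enter. KO lists called lower were 11 in place of 17 with a filter of 50, where fewer members are tested, and 7 with an estimated correlation. Dox lists were 1 higher and 1 lower with an estimated correlation in place of 8 and 12, and 4 higher with WT as the control; the cause was not tested.

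Leaving out each library in turn gave 757 to 1165 higher and 842 to 1240 lower in KO against WT, the lowest without WT 3 for the higher genes, and 1479 to 2303 higher and 1695 to 2305 lower for Dox. For OE without Dox against WT it gave 267 to 644 higher and 152 to 439 lower. The difference of effects ranged over 2055 to 2607 and 1961 to 2349, the opposed genes over 804 to 1094 and the shared over 167 to 227. KO lists ranged over 15 to 18 lower, with 2 higher throughout, and Dox lists over 8 to 9 higher and 9 to 12 lower. CTNNB1 ranged over -0.79 to -0.57 in KO, 2.90 to 3.10 with Dox and -0.29 to -0.07 between the controls. Without WT 1, KO 1 and KO 2 together, 789 were higher and 880 lower in KO.

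Of 277 named-gene results, 38 lose their call when some 1 library is left out, in 119 combinations, and RPL8 gains one with Dox without OE without Dox 2 (adjusted p = 0.041). Under edgeR 275 of 276 kept direction and side of the threshold, under DESeq2 273 of 274, under TMM 276 of 276, and under the replicate block 266 of 276. The KO results under the block use KO 1, 2 and 3 alone. DESeq2 gave no adjusted p for VCAM1 in either comparison. With OE without Dox as the control for KO, 60 of 125 kept theirs, 52 lost the call and 13 were counted as changing sign: MIR9-1HG (-0.03), HES5 (-0.43), INA (-0.13), GBX1 (-0.33), SOX9 (-0.09), BTG3 (0.00), ETV4 (0.38), FGF17 (0.00), AFDN (-0.04), DDIT3 (0.04), XBP1 (0.05), SHMT2 (0.02) and ZFP36 (0.37). BTG3 and FGF17 are counted only because their folds round to 0.00, so no sign is known for them. MIR9-1HG, AFDN, DDIT3, XBP1 and SHMT2 lie near 0, which is a lost difference more than a reversed one. With WT as the control for OE with Dox, 119 of 143 kept theirs, 21 lost it and 3 changed sign: MIR9-1HG (0.65), CLIC6 (-0.10) and GDF15 (-0.55). The cause was not tested beyond the difference of the control groups itself.

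In counts drawn at random, limma recovered 16.4% of genes changed 1.5-fold for KO against WT and 6.0% for Dox. For KO against WT the draws changed 67 of 16743 genes by 1.5-fold, 66 by 2-fold and 66 by 4-fold. That is far fewer than the 2359 genes called in the data. With fewer changed genes the adjusted threshold is stricter, so these shares need not hold in the data.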

Other observations

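TRDC, the constant region gene of the T cell receptor delta chain, was at 598 ± 269 in OE with Dox (287.6 to 763.7), with 6 reads over the WT libraries, 0 over KO and 2 over OE without Dox. The strand setting of the counting is not given, so transcription from a neighbouring or opposite unit is not excluded. GADL1 was at 288 ± 31.1 with Dox and CHRM2 at 865 ± 139, with 1 and 7 reads over the OE without Dox libraries, 8 and 7 over WT, and means of 1.12 and 2.045 in KO. These 3 genes belong to none of the lists. ZNF558 stood at 259 ± 12.5 in WT and at 21.3 ± 15.8, 7.95 ± 8.24 and 14.5 ± 11.2 in KO, OE without Dox and OE with Dox; in OE without Dox against WT its log2 fold was -5.62 (adjusted p = 0.035), and the call was lost without any 1 of the WT libraries, the OE without Dox libraries or KO 1, at adjusted p of 0.052 to 0.13. The log2 fold then ranged from -6.49 without OE without Dox 1 to -4.42 without OE without Dox 3.

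Against OE without Dox, p53 targets were higher in KO as a list, with 1 higher and 0 lower of 17 (5 and 0 adjusted over the list alone; adjusted p = 0.018 with an estimated correlation), and CDKN1A stood at 874 ± 259 against 356 ± 81.8. Against WT the list was not called in KO, and in OE without Dox it was lower than in WT at the preset correlation (median -0.42, adjusted p = 0.0037, and 0.18 with an estimated correlation).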
